A study of Homo sapiens with 2 samples.

How the data were processed

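The series holds 2 PAR-CLIP libraries from U87MG cells, an established human glioblastoma line. One library came from an immunoprecipitation of the RNA-binding protein RBM4. The other came from an immunoprecipitation of HIF-2α, from which the band of associated RBM4 was cut. Per the labels' protocols, cells were grown at 37 °C in 5% serum and given 100 μM 4-thiouridine for 14 h, starting 24 h after plating. Per the same protocols, RBM4 was captured with an antibody to the protein and HIF-2α with a GFP-binding resin, and the libraries were read as single 76-base Illumina reads. The labels give no oxygen level for the cultures, and no control or input library was used here.

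The deposited files hold counts: each line pairs a transcript description, which carries a gene symbol in brackets, with a whole number of reads. Per the file headers, the authors treated identical reads as a single read before counting, so a count is a number of distinct reads and is not scaled to depth or transcript length. The genome build NCBI36 is named in the submitters' processing notes. The aligner, the annotation release, the filters on read length and mapping, and any filter on T-to-C changes are not given in the sources used here. The total of a list is the number of reads listed, which need not be the depth of its library. The lists give no positions, strands, sequences or T-to-C values. The tests planned before the data were examined for overlap of sites, annotation classes, sequence motifs and T-to-C conversion were therefore not run, and the comparisons were made at the level of transcripts and genes.

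The symbol was taken from the last bracket before the transcript type at the end of each description. In the RBM4 file, 4 read numbers were written in scientific notation and were read as whole numbers. Entries with the same symbol were summed per gene, with the largest entry as an alternative; reads that fit several transcript variants of a gene could have been counted for each of them. Symbols were matched to a RefSeq gene table of the assembly GRCh38.p14 by current symbol or by a synonym that names 1 gene. Of the 4167 distinct symbols of the RBM4 list, 3779 matched (90.7%), and of the 1426 of the HIF-2α list, 1362 matched (95.5%). The build differs from that of the files, so no coordinates from the table are given. The table was used for current names, for the set of 20056 protein-coding genes that served as the universe of the overlap test, and for the genomic span of each gene.

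Overlap of genes was tested with Fisher's exact test, two-sided, against the protein-coding genes; this universe leaves out which genes U87MG cells express. Members of 19 gene lists fixed before the data were examined were compared between HIF-2α genes and genes of the RBM4 list alone with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the lists. Each list was also set against 10000 random gene sets drawn within 10 strata of genomic span, since no transcript lengths were given; the smallest two-sided p these draws can give is 0.0002. The numbers expected from these draws do not allow for the alphabetical stop of the low HIF-2α entries, or for a nearly empty stretch before it. Reads per shared gene were compared on a log2 scale with Pearson's r and Spearman's rho and 100000 permutations. Shares carry exact Clopper-Pearson 95% intervals and counts exact Poisson 95% intervals, and both cover counting error only. With 1 library per group there is no replicate, so no p-value is given for a single gene, and each test compares these 2 lists, not the 2 immunoprecipitations in general.

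Genes were named by a rule set before the data were examined. It takes the 10 genes with most reads in each library and the 10 with the largest geometric mean in both. It adds the proteins of the study and 3 receptors known from it, and from each fixed list up to 4 members found in both libraries and up to 4 found in one, ties by alphabet. Other genes named are marked as chosen after their values were seen. Alternatives set before the data were examined took entries at or above each list's median, as many top RBM4 entries as the HIF-2α list holds, updated symbols, another universe and another grouping of genes. The HIF-2α median was 1 read, so the first of these removed no HIF-2α entry and trimmed the RBM4 list alone. Alternatives added after the data were seen left out parts of the HIF-2α list, limited both lists to part of the alphabet, or left 3 receptors out of a gene list. The repeated lines are the entries that, at the end of a HIF-2α read number below 5, stand in the order of the RBM4 list, a definition made after the lists were seen. The order of descriptions along each list was compared between successive read numbers with at least 50 entries, with 10000 permutations; descriptions were sorted without prefix, hyphens or apostrophes.

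The statistics were tested on simulated data. In 100 simulated pairs of lists drawn from 20056 genes with 3681 and 1339 genes, the protein-coding genes of the real lists, the overlap test passed 0.05 in 4% of pairs with no excess and in 100% with 200 extra shared genes. Lists of 40 genes tested against span-matched sets passed in 2% of 100 simulations at the base rate of the RBM4 list and in 99% at 3 times the base rate. The test of alphabetical order passed in 4.5% of 200 simulations of 500 entries with random order and in 100% with order along the alphabet. The rank correlation of 200 values passed in 8.5% of 200 simulations with independent values (exact interval 5.03 to 13.3), in 5.05% of 2000 further ones, and in 100% of 200 with correlated values. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.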

Results

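RNA bound to RBM4 was profiled by PAR-CLIP in U87MG glioblastoma cells. In this assay, cells take up 4-thiouridine, protein and RNA are crosslinked by light, and the RNA that comes down with a protein is sequenced. RBM4 is an RNA-binding protein with roles in splicing and translation. HIF-2α, the product of EPAS1, is a hypoxia-inducible transcription factor subunit. The RBM4 list held 4239 transcript entries with 4167 distinct gene symbols and 25647 listed reads. The list from the RBM4 band of the HIF-2α immunoprecipitation held 1461 entries with 1426 symbols and 3290 reads. The median entry had 3 reads in the RBM4 list and 1 read in the HIF-2α list. Entries with 1 read made up 36.1% of the RBM4 list and 59.9% of the HIF-2α list, and entries with 5 reads or more 41.5% and 7.87%. Protein-coding genes of the reference table accounted for 3681 genes of the RBM4 list and 1339 of the HIF-2α list. Each group had 1 library, so no value has a replicate error.

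The 10 genes with most reads in the HIF-2α list included growth factor receptors, growth factors, cadherins and a kinase. EGFR, the receptor for epidermal growth factor, led with 33 reads (exact Poisson 95% interval 22.7 to 46.3), followed by PDGFRA, a receptor for platelet-derived growth factor, with 29 reads (19.4 to 41.6). FGF11, a member of the fibroblast growth factor family, had 27 reads. CDH23, a cadherin, and FGFR1, a fibroblast growth factor receptor, had 26 reads each. IGF1R, the receptor for insulin-like growth factor 1, had 22 reads (13.8 to 33.3). The other genes of the leading 10 were CDH22, FGF10, MAPK11, a p38 kinase, and MDK, the growth factor midkine, with 21 reads each. All 10 were also in the RBM4 list, with FGFR1 at 67 reads, FGF11 at 23, EGFR at 22, PDGFRA and FGF10 at 21, IGF1R at 18, MAPK11 at 14, MDK at 8, CDH23 at 7 and CDH22 at 6. EGFR took 10.0 of every 1000 listed reads in the HIF-2α list (exact interval 6.91 to 14.1) and 0.858 in the RBM4 list (0.538 to 1.30). PDGFRA took 8.81 per 1000 (5.91 to 12.6) and 0.819 (0.507 to 1.25), and IGF1R 6.69 (4.20 to 10.1) and 0.702 (0.416 to 1.11). These intervals cover counting error only, and the shares depend on what each list includes. The low HIF-2α entries stop partway through the alphabet, as described below. At the RBM4 share of names, 2840 low entries would be expected after that point. The HIF-2α total may therefore be too small, and the HIF-2α shares too high.

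Of the study's own proteins, EPAS1 and ARNT were listed. EPAS1 had 11 reads in the HIF-2α list (5.49 to 19.7) and 7 in the RBM4 list (2.81 to 14.4). ARNT, the dimer partner of HIF-2α, had 1 read in the HIF-2α list and was not listed for RBM4. RBM4, RBM4B, HIF1A, EIF4E2, EIF4E and EIF4A1 were in neither list. As a list, these proteins had 2 of 8 members among the HIF-2α genes and did not pass Fisher's exact test (adjusted p = 0.406). The cap-binding family member EIF4E3 had 54 reads in the RBM4 list and 19 in the HIF-2α list.

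The RBM4 list was led by FGFR1 with 67 reads (51.9 to 85.1), RIT1, a small GTPase, with 65 (50.2 to 82.8), and C20orf45 with 61. STEAP2, TMEM19 and WDR36 followed with 60 reads each, SLC25A37, a mitochondrial iron importer, with 59, and CCDC23, FGF9 and INHBA, a subunit of activin, with 58 each. Of these 10 genes FGFR1 was in the HIF-2α list, and the other 9 had no HIF-2α entry. For genes whose descriptions sort after the stop of the low HIF-2α entries, described below, this absence cannot be read as lack of binding. The same holds for C20orf45 and CCDC23, whose names fall in a nearly empty stretch before the stop. Ranked by the geometric mean of both read numbers, the leading 10 shared genes were FGFR1, EIF4E3, EGFR, FLT1 (a receptor for vascular endothelial growth factor; 32 RBM4 and 20 HIF-2α reads), FGF23 (45 and 14), FGF11, PDGFRA, BCAM (41 and 11), FGF10 and MAPK10 (27 and 15).

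**Figure D1:**
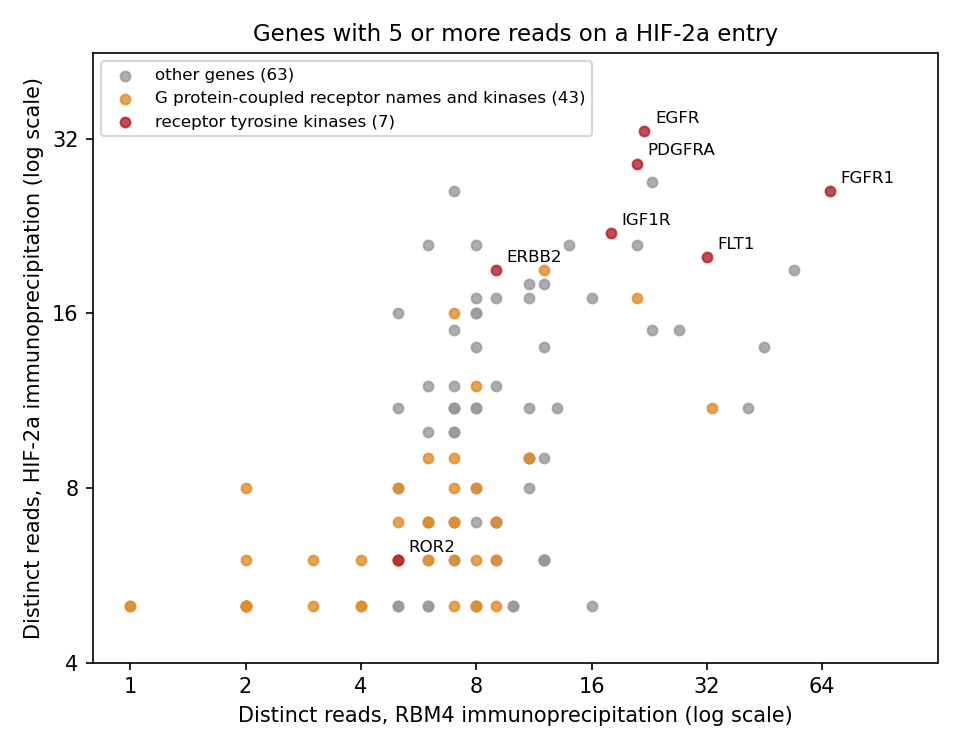
Distinct reads per gene in the RBM4 immunoprecipitation (x axis, log scale) and in the HIF-2α immunoprecipitation cut at the RBM4 band (y axis, log scale) for the 113 genes with an entry of 5 or more HIF-2α reads, 1 library each. Points are genes, coloured by group. Labels mark the 7 members of the fixed list of receptor tyrosine kinases, of which 6 had 19 or more HIF-2α reads and ROR2 had 6. The insulin receptor-related receptor INSRR, with 7 HIF-2α reads, is not in that list and is drawn among other genes.

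Receptor tyrosine kinases, the family of growth factor receptors with kinase activity, were found more often than span-matched genes in both lists. Of the 43 members of the fixed list, 22 had an entry in the RBM4 list, against 11.2 expected from random gene sets of the same genomic span (permutation test, adjusted p = 0.0051). In the HIF-2α list 15 had an entry, against 3.96 expected (permutation test, adjusted p = 0.0017, from the smallest p the draws can give). Of these 15, 10 have descriptions that sort up to the point where the low HIF-2α entries stop. A further limit is that 2 stood only in the repeated lines, and the number expected allows for neither. Entries with 5 or more HIF-2α reads included 7, against 0.292 expected (permutation test, adjusted p = 0.0017), and these were EGFR, PDGFRA, FGFR1, IGF1R and FLT1, with ERBB2 and ROR2, which were named after their values were seen. ERBB3 with 26 reads, NTRK2 with 25, TIE1 with 7 and EPHB4 with 6 were in the RBM4 list without a HIF-2α entry. Where a description sorts after the alphabetical stop, such an absence cannot be read as lack of binding. Between the lists, 15 members were among the HIF-2α genes and 9 among the genes of the RBM4 list alone, an odds ratio of 4.06 (Fisher's exact test, adjusted p = 0.00905). By the same exact test that difference was lost with entries at or above each list's median (odds ratio 2.65, adjusted p = 0.300), with as many top RBM4 entries as HIF-2α entries (odds ratio 2.26, adjusted p = 0.557), without the HIF-2α entries that repeat lines of the RBM4 list (odds ratio 3.10, adjusted p = 0.0916), and within the part of the alphabet that the low HIF-2α entries span (odds ratio 1.88, adjusted p = 1). It passed the exact test with HIF-2α entries of 5 or more reads (odds ratio 17.8, adjusted p = 2.1e-05) and for genes in both lists against genes in one (odds ratio 7.03, adjusted p = 0.000121). The median setting removed no HIF-2α entry, as the HIF-2α median was 1 read. The 43 include EGFR, PDGFRA and IGF1R, listed beforehand as receptors known from the study; all 3 had 5 or more HIF-2α reads, against 0.0195 expected (permutation test, adjusted p = 0.0017), which is not independent evidence. Without these 3, an alternative added after the results were seen, 19 of 40 members were in the RBM4 list against 10.3 expected (permutation test, adjusted p = 0.0306), 12 in the HIF-2α list against 3.64 (adjusted p = 0.0017) and 4 with 5 or more HIF-2α reads against 0.272 (adjusted p = 0.0034). The difference between the lists was then lost (12 against 9 members, odds ratio 3.24, Fisher's exact test, adjusted p = 0.0720).

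Translation factors, the proteins that start, extend and end protein synthesis, were the other list that differed. Of 58 members, 17 had an entry in the HIF-2α list against 3.65 expected (permutation test, adjusted p = 0.0017), and 9 in the RBM4 list against 10.1 expected (adjusted p = 1). The HIF-2α members included EIF4E3 with 19 reads, EIF4A2 and EIF4B with 4 each, and EIF3S10 (EIF3A) and EIF4G3 with 3 each. EEF2K, the kinase of elongation factor 2, had 2. EIF2S3 with 8 reads and EEF1A1 with 6 were in the RBM4 list alone. Against genes of the RBM4 list alone, the odds ratio was 10.4 (Fisher's exact test, 17 members against 4, adjusted p = 2.5e-05). The descriptions of all 17 HIF-2α members fell in the part of the alphabet that the low HIF-2α entries span, and with both lists limited to that part the difference was lost (exact test, odds ratio 3.21, adjusted p = 0.571). It was also lost by exact test with as many top RBM4 entries as HIF-2α entries (odds ratio 6.44, adjusted p = 0.0774), with HIF-2α entries of 5 or more reads (odds ratio 4.51, adjusted p = 0.835), and for genes in both lists against genes in one (odds ratio 1.84, adjusted p = 0.988). It passed with entries at or above each list's median (exact test, odds ratio 10.6, adjusted p = 0.00147) and without the repeated lines (odds ratio 11.2, adjusted p = 1.1e-05).

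Splicing factors and hnRNP proteins were found in the RBM4 list more often than span-matched genes, at 21 of 56 against 9.95 expected (permutation test, adjusted p = 0.0034). The members with most reads were SFRS6 (SRSF6) with 51, PTBP2, the neural polypyrimidine tract-binding protein, with 32, QKI with 28 and HNRPU (HNRNPU) with 13, and MBNL1 and others had 11. In the HIF-2α list 3 members had an entry, against 3.58 expected (permutation test, adjusted p = 1), among them SFRS6 and ELAVL1 with 1 read each. The SFRS6 entry stood only in the repeated lines. The difference between the lists did not pass Fisher's exact test (odds ratio 0.381, adjusted p = 0.561). Within the part of the alphabet that the low HIF-2α entries span, its direction turned, with 2 members among HIF-2α genes and 1 in the RBM4 list alone (odds ratio 1.12, exact test, adjusted p = 1).

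The lists of this and the next paragraph did not pass a test. Among known HIF targets, 12 of 40 were in the RBM4 list (7.08 expected, permutation test, adjusted p = 0.241) and 2 in the HIF-2α list (2.62 expected, adjusted p = 1). TGFA with 7 RBM4 reads, CCND1 with 6, TFRC with 5 and EGLN1 with 5 had the most, and EGLN1 had 1 HIF-2α read. Glycolytic enzymes had 2 of 17 members in the RBM4 list, ENO2 with 14 reads and HK2 with 3. Cytosolic ribosomal protein genes, which are transcribed at high levels in dividing cells, had 4 of 78 in the RBM4 list (7.80 expected, permutation test, adjusted p = 0.419) and 0 in the HIF-2α list; RPL23 with 11 reads and RPL5 with 5 led. The descriptions of these 4 genes sort after the point where the low HIF-2α entries stop, as do those of the neuronal markers found. In the HIF-2α list 3.15 ribosomal protein genes (permutation test, adjusted p = 0.337) and 0.977 neuronal markers were expected. Neither number allows for the stop, so the absence of these genes there cannot be read as lack of binding. Cytoskeletal genes had 13 of 40 in the RBM4 list, including ACTN4 with 44 reads and ACTB with 24, and matrix and adhesion genes 15 of 40, including COL1A1 with 49 and CDH2 with 15. Glioma genes had 11 of 33, with STAT3 at 38 and PIK3CA at 11. Of 14 transcripts tied to RBM4 in the literature, 4 were in the RBM4 list, INSR with 33 reads, PTBP2 with 32, and PTBP1 and TPM1 with 1 each. No replication-dependent histone gene and no mitochondrially encoded gene of the fixed lists was in either list, and of 24 abundant non-coding RNAs MALAT1 had 3 reads and TncRNA (NEAT1) 1 in the RBM4 list.

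Markers of other cell types were included as a check. Neuronal markers were at 5 of 12 in the RBM4 list against 2.77 expected (permutation test, adjusted p = 0.427), with SYT1 at 21 reads, GAD2 at 10 and GAD1 at 8, and at 0 of 12 in the HIF-2α list. Astrocyte markers were at 3 of 10 in the RBM4 list and 2 of 10 in the HIF-2α list, and endothelial markers at 2 of 8 in each, with PECAM1 at 12 RBM4 and 6 HIF-2α reads. Haematopoietic markers were at 1 of 12 in the RBM4 list, PTPRC with 3 reads. None of these lists passed a test.

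The design asks how far the RNA in the RBM4 band of the HIF-2α immunoprecipitation is that bound by RBM4 overall. Of the 1426 HIF-2α symbols, 710 were in the RBM4 list, or 49.8% (exact Clopper-Pearson 95% interval 47.2 to 52.4), and these were 17.0% of the RBM4 symbols. Over protein-coding genes 681 were shared, against 246 expected from independent lists, an odds ratio of 5.42 (Fisher's exact test, p = 8.43e-174). The excess does not separate shared binding from both lists drawing on the genes these cells express. The 115 entries with 5 or more HIF-2α reads, from 113 genes, were all in the RBM4 list (100%, exact interval 96.8 to 100), whereas of the 1346 entries with fewer reads 625 were (46.4%, 43.7 to 49.1). These values include the 87 repeated lines, which are in the RBM4 list by their definition. Without them 538 of 1259 lower entries were in the RBM4 list (42.7%, 40.0 to 45.5). In that setting 635 symbols were shared (odds ratio 4.74, Fisher's exact test, p = 2.6e-139). The authors' deposited table states in its header that 98 of 115 targets with 5 or more reads were also in the RBM4 list, and that 84 of these had reads overlapping at one site. Of the 113 genes, 99 had 5 or more RBM4 reads with entries summed per gene and 14 had fewer. With the largest entry of each gene in place of the sum, 98 genes had 5 or more reads in both lists, and with sums in both lists 102 had. Overlap at single sites was not analysed here.

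**Figure D2:**
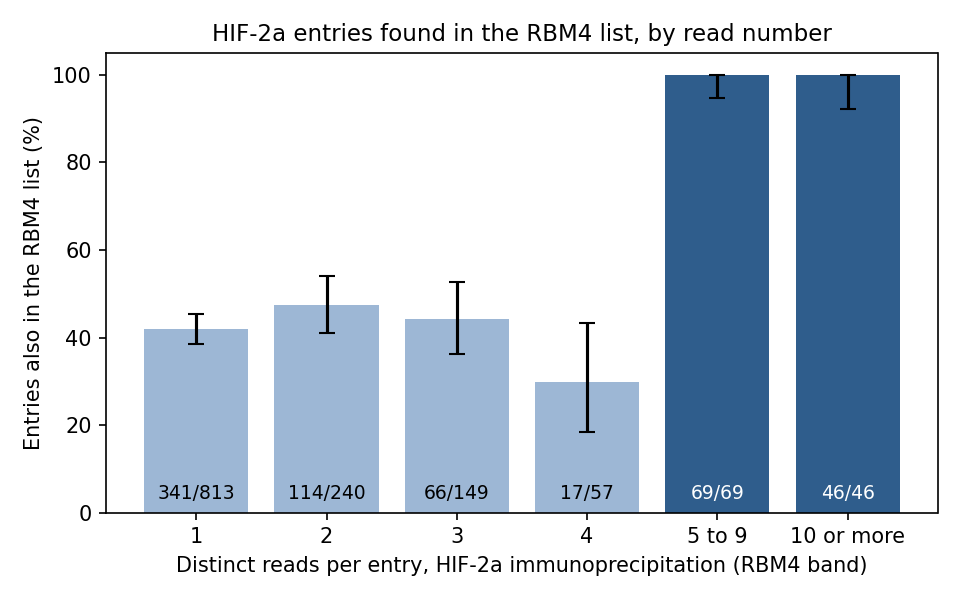
Share of HIF-2α entries whose gene was in the RBM4 list (y axis, percent) by the number of distinct HIF-2α reads (x axis), leaving out 87 entries that repeat lines of the RBM4 list. Bars are shares with exact 95% intervals for counting error, with entries found over entries in the group; the share was 41.9% at 1 read, 29.8% at 4 reads, and 100% from 5 reads.

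Across the 710 shared genes, which are not independent replicates, read numbers in the 2 lists were weakly related (Spearman's rho 0.153, permutation p = 8e-05; Pearson's r 0.163 on the log2 scale, permutation p = 3e-05). Over the 113 genes with 5 or more HIF-2α reads rho was 0.543 (permutation p = 1e-05, the smallest the permutations can give). Over the 522 shared genes with fewer reads, without repeated lines, rho was 0.038 (permutation p = 0.393). The difference between these groups was not tested. After Benjamini-Hochberg adjustment over the Spearman correlations computed, the permutation p-values were 0.000213 for all shared genes, 4e-05 for the 113 and 0.449 for the 522. With as many top RBM4 entries as HIF-2α entries, rho was -0.0066 (permutation p = 0.898), and with entries at or above each list's median it was 0.050 (permutation p = 0.266).

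The order of the lines bears on these read numbers. RBM4 read numbers were unevenly spread, with 60 entries at 8 reads, 185 at 9, 17 at 10, 287 at 11 and 24 at 12. The Poisson intervals take each number as a plain count, which was not tested. Both files run from high to low read numbers. In the RBM4 list the descriptions ran on through the alphabet across some steps in the read number: 96.3% of the 214 entries with 4 reads began with a digit or a letter from A to D, all 310 with 3 reads began with E to P, and 61.2% of the 425 with 2 reads began with Q to Z. An entry with 3 reads sorted after one with 4 reads with a probability of 0.997 (permutation p = 1e-04, the smallest the permutations can give; 0.000188 adjusted over 15 steps). The probability was 0.729 from 3 to 2 reads, 0.777 from 6 to 5 and 0.867 from 8 to 7. It was 0.052 from 5 to 4, 0.227 from 7 to 6, 0.372 from 11 to 9, 0.403 from 2 to 1 and 0.494 from 9 to 8, where the series did not run on. In the HIF-2α list the alphabet restarted at each read number from 4 to 1, and the probability was 0.621 from 4 to 3 reads (permutation test, adjusted p = 0.00764), 0.507 from 3 to 2 (adjusted p = 0.879) and 0.555 from 2 to 1 (adjusted p = 0.012). In that list the 1259 entries under 5 reads in alphabetical order stopped at GATA2, while 69.3% of RBM4 entries under 5 reads sorted after that name. At the end of each of these read numbers the alphabetical entries were followed by entries in the order of the RBM4 list, 87 in all. Before GATA2 there was also a nearly empty stretch. Of symbols from C14orf to C22orf and C2orf to C9orf, only C16orf69, C5orf22 and C6orf105 had a HIF-2α entry. Their RBM4 reads of 37, 44 and 33 lie in the range of the repeated lines, 33 to 57. No symbol starting with CCDC or CLDN had a HIF-2α entry. Tests limited to the alphabet up to the stop did not leave this stretch out. Read numbers of single genes in the RBM4 list, and absence of a gene from the HIF-2α list, are therefore given as the files state them.

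**Figure D3:**
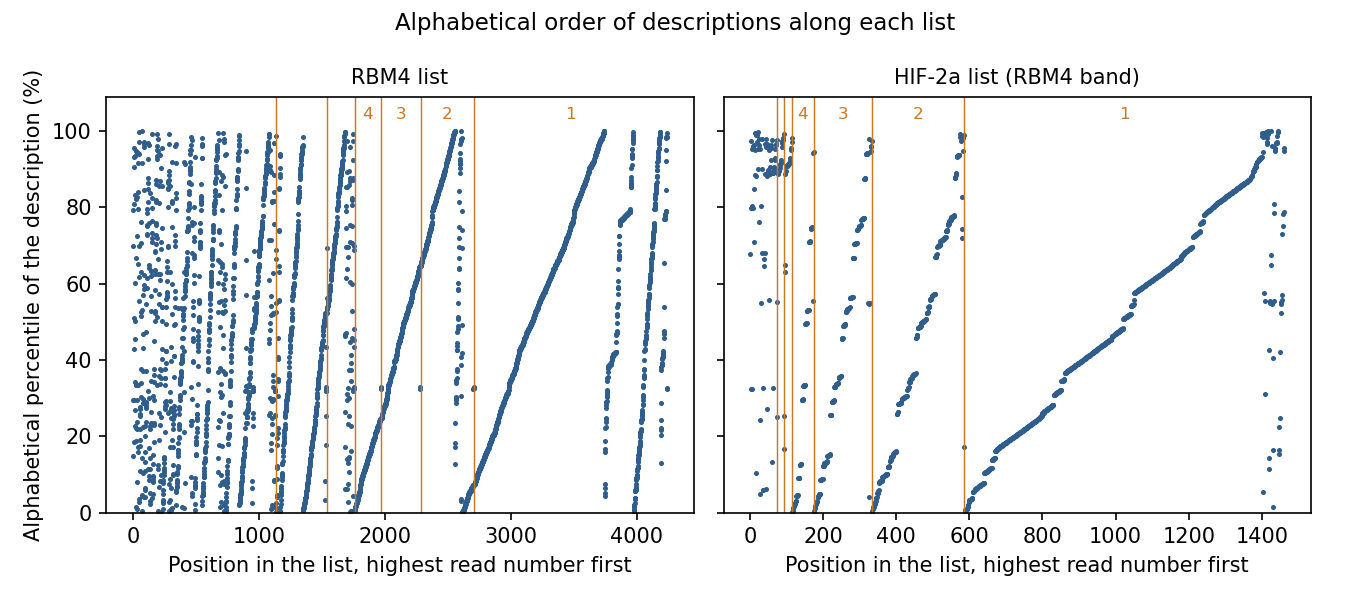
Alphabetical percentile of each description (y axis, percent) against its position in the list, highest read number first (x axis), for the RBM4 list and the HIF-2α list. Each point is an entry, and vertical lines mark steps between read numbers, with entries of 1 to 4 reads labelled at the top; the series runs across the steps from 4 to 2 reads in the RBM4 list and restarts at each step in the HIF-2α list.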

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

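Some descriptions end in a bracketed number that no header explains and that no comparison used. It stood on 181 entries of the RBM4 list, with a median of 3 and a highest value of 52, and on 15 of the HIF-2α list. All 15 HIF-2α entries carried the same number as in the RBM4 list, and all 15 were among the 87 entries in RBM4 order. This was singled out because it is a value outside the read numbers. Of the 87 entries, 12 had a symbol that also stood earlier in the HIF-2α list.

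The tests of this part were chosen after the results were seen, except the test with 1 entry per gene family. The first pattern is that RBM4 read numbers follow the alphabet. To examine whether families of similarly named genes share counts, 1 entry per family was drawn at random among the entries of 3 and 4 reads. The probability that an entry with 3 reads sorts after one with 4 reads was then 1 (220 entries with 3 reads and 137 with 4). As it was 0.997 over all entries, few pairs were out of order, and no such draw could lower it much. The draw therefore could not test the family explanation, which stays open. A candidate explanation is that read numbers and descriptions were ordered separately in parts of the file; the probability of 0.997 over all entries prompted it and so does not test it, and other steps gave values down to 0.052. The read numbers are not arbitrary throughout: over the 113 genes with 5 or more HIF-2α reads they were related to the HIF-2α reads (rho 0.543), and without G protein-coupled receptor names rho was 0.367 over 70 genes. Which other RBM4 read numbers belong to their genes stays open, and no biological explanation of any of the 3 patterns was tested.

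The second pattern is the make-up of the HIF-2α entries under 5 reads. Taking the stop from entries with 1 read alone, without repeated lines, random loss of weakly covered transcripts would leave the entries with 2 to 4 reads after it at a share like that of RBM4 entries under 5 reads (69.3%, exact interval 67.5 to 71.1) or of the whole RBM4 list (66.9%), whereas 33 of 471 did, repeated lines included (7.01%, 4.87 to 9.70). The 87 entries that follow, at the end of each read number from 4 to 1, may be lines carried over from the RBM4 list: together they were 98.9% of the 88 RBM4 lines from rank 19 to rank 106, and the line left out, FGF23, stood higher in the HIF-2α list. They carry read numbers of their own, so whether they were counted in the HIF-2α library stays open, as does the reason for the stop.

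The third pattern is the step in overlap at 5 HIF-2α reads. If a gradual gain with more reads led to the 100% at 5 reads, the share at 4 reads would come near it. The share was 41.9%, 47.5%, 44.3% and 29.8% at 1, 2, 3 and 4 reads. The exact interval at 4 reads, 18.4 to 43.4, overlaps the one at 1 read. These low read numbers ran in blocks along some names, so they may not measure the coverage of single genes. The shares therefore cannot decide whether a gradual gain took place. Whether the header's 98 may be a count of genes with 5 or more reads in both lists stays open, since that count was 99 with RBM4 entries summed per gene, 98 by the largest entry and 102 with sums in both lists. By the largest entry, the 15 genes left out were all named G protein-coupled receptor, 1 of them a receptor kinase. How entries with 5 or more reads came to be in the RBM4 list without exception stays open.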

How the results depend on the processing

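No paired analysis was possible because each group has 1 library, and none could be left out. Of 52 alternative values, 24 stayed close: tested results on their side of the threshold, counts within 1.5 times and shares within their interval. These include values that could not change, such as the 1426 HIF-2α symbols where only the RBM4 list was trimmed. The cause of the other changes was not tested except where the construction shows it. The overlap kept an odds ratio from 3.75 to 7.00 with Fisher's exact p far below 0.05 in the alternatives where it could be set against all protein-coding genes and was finite. That range leaves out the lists limited up to the alphabetical stop. There the odds ratio was 23.7, but the protein-coding genes were not limited likewise. Drawing genes by genomic span from the 4339 protein-coding genes in either list gave a ratio of 0.590 to the mean of 1155; since that universe is the union of the lists, the observed 681 is the least possible, and the draw says nothing about the overlap. Limited to entries at or above each list's median, the RBM4 list held 2271 symbols, 36.1% of HIF-2α symbols were shared, rho was 0.050 and 1 gene list passed. With as many top RBM4 entries as HIF-2α entries, 1456 symbols remained, 385 (27.0%) were shared, rho was -0.0066 (permutation p = 0.898) and 0 lists passed (3 at an unadjusted p under 0.05). The following were chosen after seeing the data. Without the repeated lines 47.0% were shared, rho was 0.229 (permutation p = 1e-05) and 1 list passed. With 5 or more HIF-2α reads, 113 symbols (100%) were shared. With fewer, without repeated lines, 42.2% were shared and rho was 0.038. Up to the alphabetical stop, 46.7% were shared and 0 lists passed (1 unadjusted). With 3 receptors known from the study left out of the receptor tyrosine kinases, 1 list passed. Over the alternatives, adjusted p by Fisher's exact test ranged from 2.1e-05 to 1 for receptor tyrosine kinases and from 1.1e-05 to 0.988 for translation factors. Alternatives by exon, untranslated region or merged site were not run, as the lists hold no positions. In the HIF-2α list 875 of 1461 entries rest on 1 read.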

Other observations

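The gene families in this part were chosen after the lists were seen. Of the HIF-2α entries with 5 or more reads, 57 of 115 (49.6%) had the word receptor in their name, kinases and substrates of receptors included, against 90 of 1259 (7.15%) of the lower entries and 291 of 4239 (6.86%) in the RBM4 list. The largest group, called numbered receptors here, were entries named G protein-coupled receptor with a number, 40 of 115 (34.8%). Most such names were given before a ligand was known. The group rests on names alone, and what each gene encodes was not checked. Such entries were 1.35% of the lower HIF-2α entries and 1.25% of RBM4 entries. GPR110 had 17 HIF-2α and 21 RBM4 reads, GPR176 16 and 7, and GPR120 11 and 33. Of the 50 numbered receptors in the RBM4 list, 40 had 5 or more HIF-2α reads, as had the receptor kinases GRK4, GRK5 and GRK6. ADRBK1 (GRK2), a receptor kinase under another name, had 6 RBM4 reads and no HIF-2α entry. Among RBM4 genes the odds ratio for the numbered receptors was 222 (Fisher's exact test, two-sided, p = 8.37e-57, adjusted 8.37e-56 over 10 name families). Within the part of the alphabet that the low HIF-2α entries span, it was 79.0 against the lower HIF-2α entries (exact p = 1.52e-41, adjusted 1.52e-40).

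Smaller families showed the same direction among RBM4 genes. Cadherins with 5 or more HIF-2α reads were 4 of 8 (adjusted p = 6.6e-05), mitogen-activated protein kinases 3 of 6 (adjusted p = 0.00061), ADAM metallopeptidases 3 of 9 (adjusted p = 0.00207), fibroblast growth factors 3 of 13 (adjusted p = 0.00569) and RAB GTPases 3 of 19 (adjusted p = 0.0152), each by Fisher's exact test. Against the lower HIF-2α entries, within the part of the alphabet they span, the adjusted p by exact test was 0.0098 for cadherins, 0.0200 for fibroblast growth factors and 0.0604 for ADAM metallopeptidases, which did not pass; kinases of the mitogen-activated family and RAB GTPases sort outside that part. Genes with growth factor in their name were 15 of 49 (exact test, adjusted p = 3e-12). Zinc finger genes were 0 of 138, which did not pass (exact p = 0.0537). Other members with a tie to hypoxia or to EGFR, also chosen after their values were seen, were HIF1AN, the inhibitor of HIF-1α, with 18 HIF-2α and 12 RBM4 reads, EPS15L1 with 12 and 9, EPS8 with 11 and 8, and ECOP with 11 and 7. These families were picked from the lists they were tested on, and the lists carry no measure of expression.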
